A study of Homo sapiens with 4 samples.

How the data were processed

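RNA from Huh7 cells transfected with either plasmid was extracted with an RNeasy kit, amplified, converted to single-stranded cDNA, fragmented and labelled with biotin for Affymetrix whole-transcript arrays, per the labels' protocols. The authors deposited 1 table of processed values with 4 columns, 1 per array, and the scanner files were not used here. The Transcriptome Analysis Console is named per the submitters' processing notes; its version, the summarization method, the normalization and the annotation are not given in the sources used here. The deposited values were read as log2 signals, and the base was inferred from them: as natural logarithms the largest values would stand for 82224 to 84779, above the 65535 that a 16-bit scanner records. The table showed array medians of 0.615 to 0.629 and largest values of 11.3, so the arrays lay on a near-equal scale and no further normalization was applied. It carried no detection calls, background values or scan dates, so neither a batch nor a detection limit could be read from it, and probe sets that serve as array controls are not marked and stayed in the tests. Processing that shrinks dim signals, as background correction on such arrays can, would lower the differences of dim genes.

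Samples were grouped by their titles into 2 STYK1 and 2 control arrays. Nothing in the labels says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The replicates were compared first: the control arrays held equal values at 242 probe sets and the STYK1 arrays at 171, against 170 to 227 for pairs from different groups, so no array was a copy of another.

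Probe sets were named from the array platform's annotation as given for this work. Of 53617 probe sets, 23871 had exactly 1 gene symbol (313 of them listing it more than once, which was counted as 1 symbol), 1842 had several and 27904 had none here; the last 2 kinds were tested but not named. Of the named ones, 22569 were matched by Entrez ID to the RefSeq gene table of the assembly GRCh38.p14, used for names and biotypes only, which updated 90 symbols. This gave 22395 genes, each represented by its probe set with the highest mean over the 4 arrays. The files name no genome build, so no coordinates are given.

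Groups were compared with limma (version 3.58.1, R 4.3.3): lmFit with the group as the only term and eBayes without a trend, two-sided, with Benjamini-Hochberg adjustment over all 53617 probe sets and a threshold of 0.05. The model had 2 residual degrees of freedom per probe set and a prior of 2.71. Counts are also given at an unadjusted p under 0.05, alone and with a 2-fold difference. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists, with an estimated correlation and fry beside it. Of 869 listed genes 742 were measured, 7 of them mitochondrial genes found under another symbol through RefSeq synonyms. Counting a repeated symbol as 1 and the search among synonyms, without which the mitochondrial list had no measured member, were decided after first results were seen. The lists covered liver functions, cell cycle, signalling pathways, stress and metabolic programmes, RNA quality and markers of other cell types.

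The genes named in the text follow a rule set, with the tests, lists and alternatives, before the data were examined. STYK1 comes first, followed by up to 10 genes per direction whose groups do not overlap. Those with an adjusted p under 0.05 rank by size, and places left go to the smallest unadjusted p, given as not passing. Symbols that start with LOC, LINC, MIR, SNOR, SCARNA, RNU, RN7S, RNA5S, RNY, RNVU, OTTHUMG or ENSG or end in -AS stay out, which removes many unplaced loci, small RNAs and antisense genes. RN5S405, a 5S ribosomal RNA locus under another prefix, is not among them and stayed in. From a list that passed up to 4 members are named, by smallest p, and from each other list up to 2, by largest difference. The floor was chosen after seeing the data: it is the 95th percentile per array of 423 olfactory receptor probe sets, genes not expected in liver cells. Where a group lay under it on both arrays, the fold was computed against the higher of the floor and the measured signal and is given as a lower bound. The filter at the floor, the RNA classes, the splits of the arrays and the tests on ATF4 target genes were also chosen after seeing the data.

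The tests were tried on simulated data with the spread of these arrays. For STYK1 against control over 53617 probe sets, 50 were changed at each size, all in the same run and with a mean signal above 2. Of these, 18% were recovered at a log2 change of 1, 82% at 2, 98% at 3 and 100% at 5, with 12 false calls in all. The adjusted threshold is stricter where fewer probe sets change, and 1 passed in the real data. The shares recovered therefore do not carry over to those data. A simulated list of 20 genes shifted by 0.3 among 20000 probe sets was called with the preset correlation and not with an estimated one or by fry, and 0 of 40 unshifted lists were called. The simulated genes varied independently, while the estimated correlation was 0.511 for G1/S and DNA replication and 0.381 for replication-dependent histones. The simulation therefore cannot show how often the preset correlation calls unshifted lists of correlated genes. Alternatives were the replicate number as a block, quantile normalization, median centring, filters on dim probe sets, a variance trend with and without a robust prior, leaving out each array, 1 probe set per gene, an adjusted p under 0.10, limma's treat against a fold of 1.2, and for lists an estimated correlation, ranks, fry and the mean of a gene's probe sets. No outlier rule was applied, since the groups hold 2 arrays each.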

Results

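Huh7, a human cell line from a hepatocellular carcinoma, was transfected with a plasmid carrying human STYK1 (pcFLAG-hSTYK1) or with the plasmid pcFLAG, and RNA was profiled on biotin-labelled whole-transcript arrays. The comparison asks which transcripts differ when STYK1, a receptor-like kinase also known as NOK, is overexpressed. The table held 2 STYK1 arrays and 2 control arrays, with a log2 signal for 53617 probe sets on each. The number of arrays limits the precision, and the median standard error of a difference between the groups was 0.11 log2 units. Array medians lay between 0.615 and 0.629, and Pearson correlations between arrays lay between 0.985 and 0.987 both within and between the groups. The floor, a level under which a signal was taken as background, was the 95th percentile of 423 olfactory receptor probe sets and lay between 0.725 and 0.774 on the 4 arrays. Secreted proteins of hepatocytes had a median signal of 9.14 over 19 measured genes, markers of hepatoblasts and liver cancer 6.43 over 14 and hepatocyte transcription factors 3.91 over 11. Genes of drug and bile acid metabolism had a median of 0.63, under the floor, with 9 of 19 above it.

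STYK1 itself rose far above every other difference with a gene name. Its signal was 7.63 ± 0.32 (SD, n = 2) in the STYK1 arrays and 0.44 ± 0.25 (SD, n = 2) in the control arrays, a log2 difference of 7.19 with a standard error of 0.20 (limma, adjusted p = 0.0373). The controls read 0.26 and 0.61, both under the floor, so the difference is a bound: STYK1 was at least 118-fold higher in the STYK1 arrays. STYK1 replicate 1 read 7.40 and STYK1 replicate 2 read 7.86. The direction held without any single array, with fitted differences of 6.96 to 7.42, but the call did not: the adjusted p was 0.558 without control replicate 1, 0.347 without control replicate 2, 0.427 without STYK1 replicate 1 and 0.724 without STYK1 replicate 2.

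**Figure D1:**
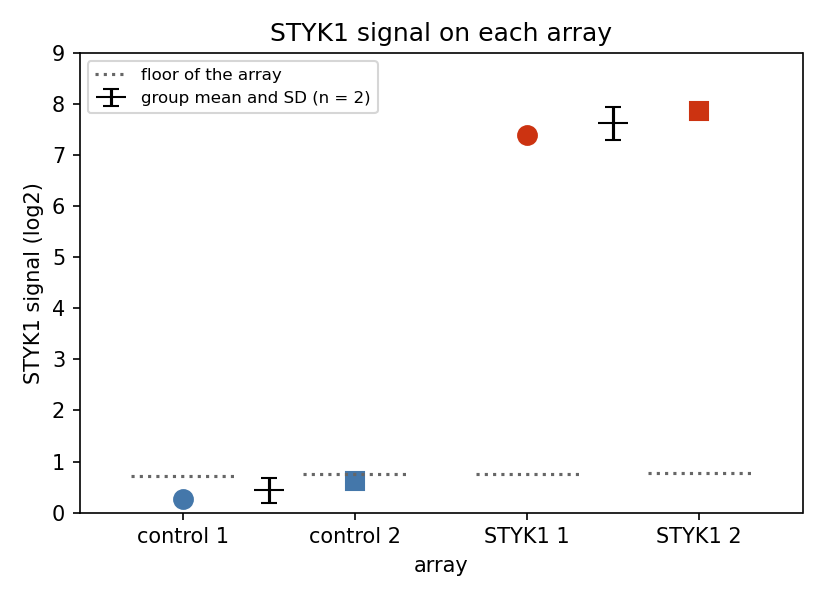
STYK1 signal on the log2 scale for each array, with the group mean and SD (n = 2) in black and the floor of each array as a dotted line. The control arrays read 0.26 and 0.61, under their floors, and the STYK1 arrays read 7.40 and 7.86.

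Beyond STYK1, no transcript passed the test, and of the named genes that came nearest, MCTS2 differed by over 2-fold and the others by less. MCTS2, a retrotransposed copy of the translation factor gene MCTS1, read 3.57 ± 0.07 (SD, n = 2) in the STYK1 arrays and 2.26 ± 0.18 (SD, n = 2) in the controls, a difference of 1.31 with a standard error of 0.12, and it did not pass (limma, adjusted p = 0.497). VCF1, a nuclear cofactor of the ATPase VCP, was 0.85 higher, and MPPE1, an enzyme that remodels GPI anchors, was 0.56 higher. ITFG2, a subunit of the KICSTOR complex that acts on mTORC1, was also 0.56 higher. On the lower side, CCDC134 differed by −0.84, the actin nucleator SPIRE2 by −0.82, SSBP4 by −0.70 and FRAT2, which binds GSK3 in the WNT pathway, by −0.52.

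The other genes that the naming rule picked were ZC3HAV1L, TMEM183BP, RN5S405, GPATCH11 and KIAA0232 on the higher side, and RNF126P1, DPY19L2, NBPF4, MYOZ3, FAM171A2 and TMEM250 on the lower side. Over all 19 genes named beside STYK1, the 9 higher ones differed by 0.48 to 1.31 and the 10 lower ones by at most 0.84 in size, with adjusted p-values of 0.497 to 0.979 (limma). DPY19L2 and NBPF4 lay under the floor on both STYK1 arrays, so they are given only as at least 1.27-fold and at least 1.22-fold higher in the controls. TMEM183BP and RNF126P1 are pseudogenes, MCTS2 is a copy of MCTS1 and NBPF4 belongs to a family of close copies, so their signals may hold transcripts of related genes.

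**Figure D2:**
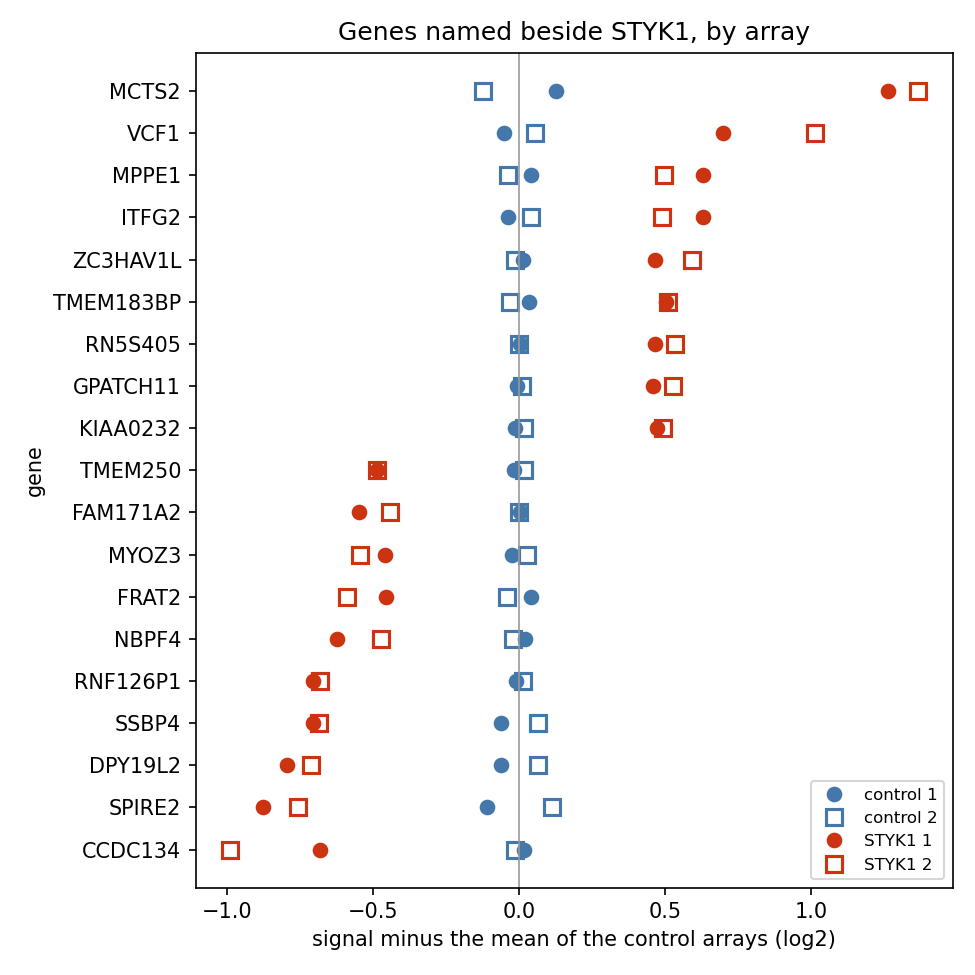
Signal of the 19 genes named beside STYK1 on each array, as the difference from the mean of the control arrays in log2 units, with 1 symbol per array. The STYK1 arrays lie apart from the controls for each gene because the naming rule asks for it, from MCTS2 at 1.31 on average to CCDC134 at −0.84.

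Counted over the 53617 probe sets, limma found 1 higher and 0 lower at an adjusted p under 0.05, and the next smallest adjusted p was 0.108. At an unadjusted p under 0.05 there were 2489 probe sets, 1463 higher and 1026 lower, where 2681 are expected by chance. Adding a 2-fold difference left 176 probe sets, 122 higher and 54 lower. That count was 309 without control replicate 1, 325 without control replicate 2, 333 without STYK1 replicate 1 and 357 without STYK1 replicate 2, and in each case 0 passed the adjusted threshold. Parting the 4 arrays in ways that do not follow STYK1 also gave such probe sets. Replicate 2 against replicate 1 gave 105 past 2-fold and 2129 at an unadjusted p under 0.05 (limma). Control 2 and STYK1 1 against the others gave 135 and 2889. Of the 176 for STYK1 against control, 171 had no gene symbol here, a share of 97.2%, against 52.0% of all probe sets. The 4 with a symbol were STYK1, MCTS2, the small nucleolar RNA SNORD53 (1.12 higher) and the Y RNA pseudogene RNY4P18 (1.06 higher), of which the last 2 fall outside the naming rule and were picked after their values were seen. The groups did not overlap for 17597 probe sets, or 32.8%, and chance alone gives 33.3%. An exact two-sided permutation test of 2 arrays against 2 cannot go below p = 0.333, so none is given per gene.

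Genes of DNA replication and replication-dependent histone genes tested lower as lists in the mean of the STYK1 arrays, by little and mainly through STYK1 replicate 1. Of the 23 measured genes of G1/S and DNA replication, 18 were lower and 5 higher, with a median difference of −0.14 (camera, adjusted p = 0.0332; adjusted p = 0.981 with an estimated correlation). Its members include E2F1, a transcription factor of S phase entry, which read 3.72 ± 0.24 against 4.15 ± 0.003 in the controls (SD, n = 2), the replication licensing factor CDT1 (difference −0.40), the flap endonuclease FEN1 (−0.39) and cyclin E1, CCNE1 (−0.35), whose groups overlapped. Of 43 listed histone genes 13 were measured, 10 of them above the floor. Of the 13, 10 were lower and 3 higher, with a median of −0.14 (camera, adjusted p = 0.0332, and 0.981 with an estimated correlation). Among the lower ones were H2BC14 (−0.59) and the linker histones H1-2 (−0.47), H1-5 (−0.45) and H1-4 (−0.29). No member of either list passed over all genes, and 0 passed adjusted over the list alone. Genes of G2/M and mitosis leaned the other way, with 17 of 24 higher and a median of 0.09 (camera, adjusted p = 0.075), for example ASPM at 0.33 and TTK at 0.28. Their mean deviation was 0.02 in control replicate 1, −0.10 in control replicate 2, 0.02 in STYK1 replicate 1 and 0.06 in STYK1 replicate 2, so the groups overlapped and control replicate 2 lay lowest.

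STYK1 replicate 1 carried most of the difference in both lists that passed. The mean deviation from each gene's mean over the 4 arrays was −0.27 in that array for G1/S and DNA replication, against 0.11 in STYK1 replicate 2 and 0.14 and 0.01 in the controls. For the histones it was −0.24 in STYK1 replicate 1, 0.06 in STYK1 replicate 2 and 0.10 and 0.08 in the controls. In the same array, ATF4 target genes deviated by 0.31 and chaperones of the unfolded protein response by 0.25. Without STYK1 replicate 1 the median of G1/S and DNA replication turned to 0.036 (adjusted p = 0.886), and that of the histones was −0.09 (adjusted p = 0.886). Without control replicate 1 the adjusted p was 0.483 for G1/S and DNA replication and 0.114 for the histones, and without control replicate 2 it was 0.0571 for the histones.

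**Figure D3:**
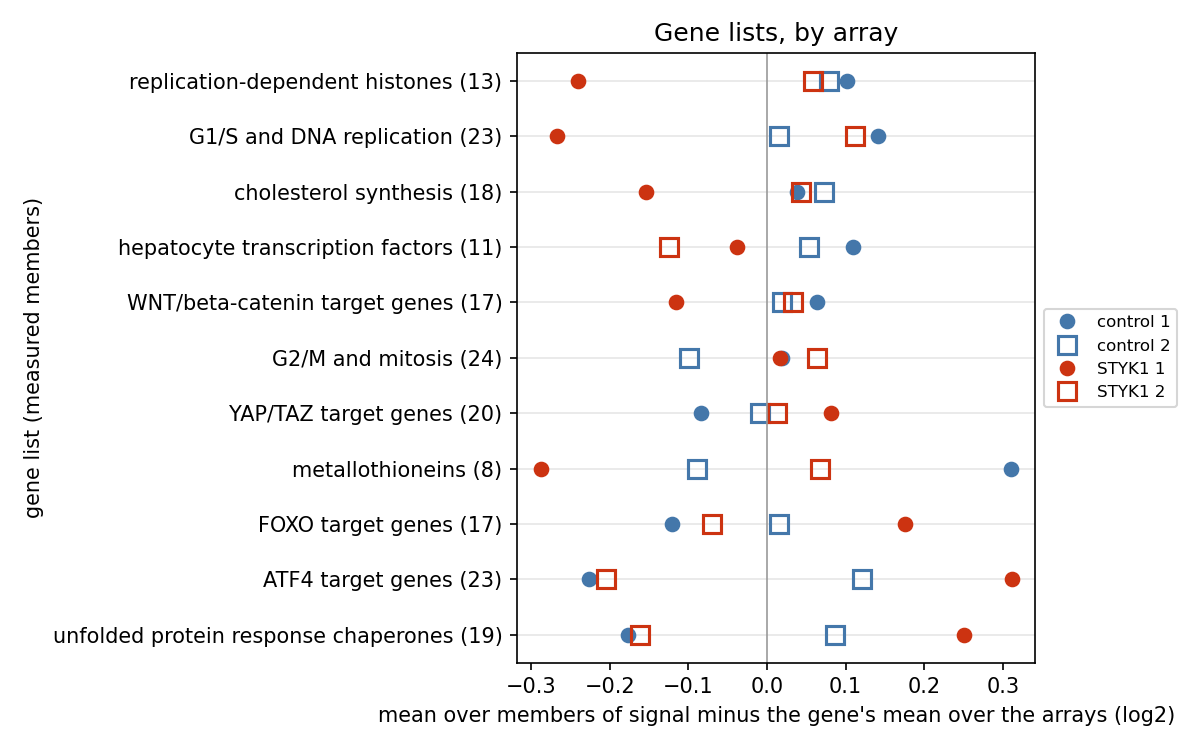
Mean deviation of each list's members from their means over the 4 arrays, in log2 units, for the 10 lists with the smallest camera p and the unfolded protein response chaperones, with 1 symbol per array and the number of measured members in parentheses. STYK1 replicate 1 lies at −0.27 for G1/S and DNA replication and at 0.31 for ATF4 target genes, and STYK1 replicate 2 at 0.11 and −0.21.

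Liver function and lipid metabolism gave no list past the threshold. Hepatocyte transcription factors were lower for 8 of 11 members, with a median of −0.15 (camera, adjusted p = 0.075), with FOXA3 at −0.82 with a standard error of 0.34 and FOXA2, whose groups overlapped, at −0.26. FOXA3 read 3.06 and 3.05 in the controls, 2.73 in STYK1 replicate 1 and 1.73 in STYK1 replicate 2, so the last array carried most of its difference. The mean deviation of the whole list was 0.11 and 0.05 in the controls and −0.04 and −0.12 in STYK1 replicates 1 and 2. The groups thus did not overlap in the list mean, which chance alone gives in 33.3% of cases. Cholesterol synthesis was lower for 13 of 18 members, with a median of −0.08 (adjusted p = 0.054). The list lay lowest in STYK1 replicate 1, at a mean deviation of −0.15, against 0.04 in STYK1 replicate 2. Its members MVK, mevalonate kinase, and INSIG1, which holds back SREBP processing, differed by −0.74 and −0.32. Secreted proteins of hepatocytes had a median of −0.04 (adjusted p = 0.402), with AMBP at −0.27. Drug and bile acid metabolism had a median of −0.03 (adjusted p = 0.402) with most members not above the floor, and CYP1A1, a dioxin-inducible cytochrome, differed by −0.49. Markers of hepatoblasts and liver cancer had a median of −0.004 (adjusted p = 0.959), with the transcription factor SALL4 at 0.29 and the growth factor MDK at −0.26. SALL4 read 0.67 and 0.80 in the controls, the former under the floor and the latter just above it, so its difference lies near background. Fatty acid synthesis and storage (median −0.01) and fatty acid oxidation (−0.0007) both had an adjusted p of 0.959, and glycolysis (median 0.004, adjusted p = 0.944) and nuclear oxidative phosphorylation genes (−0.01, adjusted p = 0.963) lay as close to 0.

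Signalling and identity lists also stayed short of the threshold. YAP/TAZ target genes were higher for 14 of 20 members, with a median of 0.12 (camera, adjusted p = 0.075) and CCN1 and AMOTL2 at 0.30 and 0.33. WNT/beta-catenin target genes were lower for 13 of 17 members, with a median of −0.07 (adjusted p = 0.075), among them BMP4 at −0.28 and AXIN2, a feedback inhibitor of the pathway, at −0.23. FOXO target genes had a median of 0.09 (adjusted p = 0.184), with IGFBP1 at 0.52 and a standard error of 0.85 and the insulin receptor substrate IRS2 at 0.31. In STYK1 replicate 1 the mean deviation was −0.12 for the WNT list and 0.18 for the FOXO list, against 0.03 and −0.07 in STYK1 replicate 2. STAT3 and acute phase genes had a median of −0.05 (adjusted p = 0.402), with the receptor IL6R at −0.63 and hepcidin, HAMP, at −0.40. The groups overlapped for HAMP, which read 4.98 and 4.39 in the controls and 4.01 and 4.57 in the STYK1 arrays. They did not overlap in the mean deviation of the STAT3 list, at 0.06 and 0.03 in the controls and −0.04 and −0.05 in the STYK1 arrays. NF-kB genes had a median of 0.06 and BCL2 family regulators one of −0.08, each with an adjusted p of 0.402. EGFR family genes had a median of −0.04 (adjusted p = 0.72), with IRS2 at 0.31 and the adaptor SHC1 at −0.28. Target genes of ERK (median 0.001) and TGF-beta (0.005), both at an adjusted p of 0.959, and of NOTCH (0.005, adjusted p = 0.963) had medians near 0. Epithelial genes (median −0.01, adjusted p = 0.462) included CRB3 at −0.34 and KRT19 at −0.26. Mesenchymal genes (0.004, adjusted p = 0.944) included MMP14 at −0.44 and N-cadherin, CDH2, at −0.32.

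Stress and clearance lists did not differ past the threshold either. ATF4 target genes had a median of 0.07 (camera, adjusted p = 0.224), with PPP1R15A, the stress-induced regulator of eIF2alpha phosphatase, at 0.70 and a standard error of 0.17. Unfolded protein response chaperones had a median of 0.10 (adjusted p = 0.402), with DNAJC3 at 0.34. Metallothioneins were lower for 7 of 8 members, with a median of −0.24 (adjusted p = 0.0837) and MT1X at −0.56; their mean deviation was −0.29 in STYK1 replicate 1 and 0.07 in STYK1 replicate 2. Hypoxia genes had a median of 0.04 (adjusted p = 0.535), and heat shock (0.06), p53 (0.002) and ferroptosis (0.002) genes each had an adjusted p of 0.944. NRF2 target genes (median 0.03), autophagy genes (0.03) and interferon-stimulated genes (0.005) had adjusted p-values of 0.959, 0.959 and 0.963, and lysosomal genes (−0.03) one of 0.963. Of the interferon-stimulated genes 13 of 37 lay above the floor, and of the NOTCH and mesenchymal genes 6 of 12 and 10 of 20, so medians near 0 rest partly on members without a signal above background. Ribosomal protein genes (median 0.03, adjusted p = 0.441) and mitochondrially encoded genes (0.09, adjusted p = 0.402) did not pass. For ERK, NOTCH, interferon-stimulated, mesenchymal and ferroptosis genes and for epithelial markers of other organs, camera's direction was lower while the median lay above 0; the mean was also above 0 for NOTCH and interferon-stimulated genes. For the hepatoblast and liver cancer markers camera's direction and the mean were higher while the median lay below 0.

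Markers of other cell types lay near the floor by their medians, and no list of them passed. Over the 4 arrays the median signal was 0.53 for endothelial markers, 0.60 for fibroblasts and stellate cells, 0.67 for immune cells, 0.66 for epithelial lines of other organs and 0.79 for cholangiocytes, where the mean floor was 0.75. In the same order, the median differences between the groups were −0.005, −0.02, −0.02, 0.02 and −0.002, with adjusted p-values of 0.959, 0.485, 0.963, 0.959 and 0.959 (camera). Of 18 measured immune markers 7 lay above the floor, among them LYZ at 7.98 in the STYK1 arrays and 7.93 in the controls, CD68 at 3.94 and 3.85 and CD14 at 2.04 and 2.11, and of the epithelial markers VIL1 read 5.17 and 5.29; these 4 genes were picked after their values were seen.

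Of the 42 lists, camera passed 2, both lower, and had 9 at an unadjusted p under 0.05. With an estimated correlation 0 passed, with an adjusted p of 0.981 for each list, and 0 had an unadjusted p under 0.05. By fry 0 passed, with 1 list at an unadjusted p under 0.05, the hepatocyte transcription factors, and by its mixed test 0 passed, with 1 at an unadjusted p under 0.05. A simulated list with a true shift of 0.3 was likewise not called with an estimated correlation or by fry. Their lack of passes therefore cannot exclude a shift of that size.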

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

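The filter at the floor was chosen after seeing the data; the other alternatives were planned. The difference in STYK1 kept its direction in all 12 alternatives run for it, from 6.96 to 7.42, and the adjusted p ranged from 2.93e-04 to 0.724. Leaving out 1 array at a time, where the lone array of a group is assumed to vary like the other group, ended its call each time (difference 6.96 to 7.42) and gave 0 changed probe sets (lowest 0, highest 0), 309 to 357 past 2-fold and an unadjusted p, and 1 to 9 gene lists; with 3 arrays 1 residual degree of freedom is left. Nothing in the labels says that the same numbers in both groups mark a shared culture or day. Deviations of same-numbered arrays correlated at −0.044 over all probe sets and −0.0526 above the floor. These values show no shared shift over the probe sets as a whole, and they cannot exclude pairing, since a shared shift may touch few probe sets. With the replicate number as a block the STYK1 difference was 7.19 with an adjusted p of 0.0637, and 0 probe sets, 204 past 2-fold and 3 lists passed; the block leaves 1 residual degree of freedom, and the cause was not tested. Restricting to probe sets with 1 symbol and 1 per gene left 4 past 2-fold, since most had no symbol. The 2 lists became 0 with an estimated correlation, 0 on ranks, 0 with fry and 0 among the probe sets above the floor. Camera on ranks fell just short, with an adjusted p of 0.0556 for G1/S and DNA replication and 0.0605 for the histones. Above the floor camera gave 0.0755 for both. The adjusted p was 0.981 with an estimated correlation and 0.982 with fry, settings that also missed a simulated shift of 0.3. The cause was not tested. The list G1/S and DNA replication reversed to 0.036 without STYK1 replicate 1, the highest of the values without 1 array, and was lowest at −0.34 without STYK1 replicate 2; its adjusted p ranged from 2.09e-09 to 0.982 over the alternatives, and that of the histones from 3.67e-06 to 0.982. Among the 28 alternatives for the lists that passed, 15 kept the call, 12 lost it in the same direction and 1 reversed, and all 228 for the other named genes kept direction and stayed short of the threshold. Quantile normalization and median centring changed the call of neither STYK1 nor these lists, and the median over all probe sets was 0.006, −0.004 and 0.0009 under the deposited scale, quantile normalization and median centring. Camera offers no robust prior, so that setting was not run for lists. Signal over background limits STYK1 in the controls to a bound, and 19282 probe sets lay above the floor in both arrays of a group.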

Other observations

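The splits of the 4 arrays, the tests on the ATF4 target genes and those on the lists that passed were chosen after the results were seen, as were the RNA classes; the tests on pseudogene copies were not. Genes of the integrated stress response varied within the groups, and the genes named here were picked after their values were seen. ASNS, asparagine synthetase, read 4.54 and 4.96 in the controls and 5.59 and 4.62 in STYK1 replicates 1 and 2. DDIT3 read 2.24, 2.78, 2.92 and 1.77, and SESN2 read 4.89, 5.43, 5.68 and 4.72, in the same order. The ER chaperone gene HSPA5 read 9.09, 9.48, 9.80 and 9.19. IGFBP1, a secreted binder of insulin-like growth factors, had the widest spread among these, at 4.34 ± 0.90 in the controls and 4.86 ± 1.61 in the STYK1 arrays (SD, n = 2).

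By RNA class, no group of transcripts stood apart between STYK1 and control arrays. Small nucleolar RNAs had a median difference of −0.05 over 213 genes (camera, adjusted p = 0.514), the lowest p of 7 classes. Protein-coding genes had a median of 0.003 over 17025, long non-coding RNAs 0.001 over 1989 and microRNA genes 0.004 over 1018. The share of probe sets without a symbol among those past 2-fold was 97.2% for STYK1 against control, and 96.2% and 90.4% for the other ways of parting the arrays into pairs.

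The first pattern weighed is a shift of ATF4 target genes between arrays of the same group: their mean deviation was −0.23 in control replicate 1, 0.12 in control replicate 2, 0.31 in STYK1 replicate 1 and −0.21 in STYK1 replicate 2. Of the 3 splits of the arrays into pairs, the one that sets control 2 and STYK1 1 against the others gave 9 lists past the threshold, against 0 and 2 for the other splits. ATF4 targets, unfolded protein response chaperones, G1/S and DNA replication and histones were among the 9. These calls use the preset correlation of 0.01, where the estimate was 0.687 for the ATF4 list, and with an estimated correlation 0 lists passed in any split. That setting also missed a simulated list with a true shift of 0.3, so its lack of calls does not speak against the pattern. An array-wide difference in intensity or normalization is argued against as the whole cause, since after quantile normalization the list's median in that split was still 0.497, with 22 of 23 members up, where 95% of 10000 random lists of like signal lay between −0.065 and 0.080. An exchange of a control and a STYK1 sample is argued against by STYK1 itself, as the lowest STYK1 array lay 6.79 above the highest control, and no biological explanation was tested.

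The second pattern is the lower result of the lists for G1/S and DNA replication and for histones. Of the 3 splits, 2 gave at least as many lists, with 2 in the real one and 9 as the highest of the others, and 3 splits are too few for a share under 0.05. Both lists also tested lower in the split of control 2 and STYK1 1 against the others, which does not follow STYK1. There G1/S and DNA replication had a median of −0.22 (camera, adjusted p = 3.06e-07), against −0.14 and 0.0332 in the real split. The histones had a median of −0.17 (camera, adjusted p = 0.0203), against −0.14 and 0.0332. For G1/S and DNA replication the arrays' list means overlapped, with a gap of −0.097 between the groups against 0.38 between the STYK1 arrays, so the spread between arrays of a group could account for that difference. For the histones the gap was 0.020 against 0.30 within a group, so the spread between arrays and an effect of STYK1 cannot be told apart with 2 arrays each. An effect of STYK1 stays open for both lists.

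The third pattern is that some transcripts known to be abundant had low signals on all 4 arrays, with means of 1.57 for GAPDH, 1.86 for ACTB, 1.22 for KRT8, 1.69 for KRT18 and 1.58 for TUBA1B, while others had high ones, with 9.79 for EEF2, 10.3 for FTL, 10.5 for ALB and 10.2 for APOB, all picked after their values were seen. Close copies in the genome were tested as an explanation through the number of named pseudogenes, which was 0 for TUBA1B and 20 for FTL. Spearman's rho between that number and the signal was −0.323 across 46 ribosomal protein genes (permutation p = 0.0289) and −0.135 across 45 genes of glycolysis and oxidative phosphorylation (permutation p = 0.379), and adjusted over these 2 relations neither passed (adjusted p = 0.0579 and 0.379). Before adjustment the ribosomal protein genes met the prediction set in advance for pseudogene copies. The metabolic genes met neither that prediction nor its opposite. Signals of different probe sets cannot be ranked against each other and genes are not independent replicates, so these values leave the explanation open, and no biological explanation was tested.

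As values, 1 of the 3 splits gave as many changed probe sets as STYK1 against control, with 1 in the real one and 0 as the highest of the others, and 3 splits are too few for a share under 0.05.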
